A study of Homo sapiens with 6 samples.

How the data were processed

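The samples were 6 RNA-seq libraries of SKMEL2 cells, 3 from cells infected with a lentiviral CRISPR vector carrying a non-targeting guide RNA and 3 from cells infected with the same vector carrying a guide against GRAMD1B, all selected in puromycin before harvest. Groups and replicate numbers were taken from the sample titles. The submitters' design text describes the 3 samples of each group as biological triplicates; whether these were separate infections or parallel cultures of one infected pool is not given in the sources used here, so p-values measure the spread between these samples.

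The main table holds normalized counts, a signal per gene and library, which the authors made with DESeq2 per the labels. Per the submitters' processing notes, Salmon, DESeq2 and the human genome build hg38 were used, without versions; the annotation and the settings of both tools are not given in the sources used here. The values were taken as estimated reads per gene divided by a normalization factor and are not whole reads; whether that factor also holds a correction per gene, such as for transcript length, is not given in the sources used here. A second table, also deposited, lists only genes whose adjusted p-value in the authors' own test was below 0.05. In that deposited table the mean normalized count is a signal, the fold change and its standard error are on the log2 scale, and the test statistic is a score, per the file headers. The mean in it lay within 1e-06 of the mean of the 6 libraries of the main table for each of its 1652 genes, and the sign of each fold change was that of the group means.

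Part of the low values of each library lay at multiples of one step, taken as the worth of a single read: 0.863 normalized counts in control replicate 2 to 1.18 in knockout replicate 3. Dividing the library totals by these steps gave 20800000 to 26500000 reads per library, an approximation that holds only if each library has a single step. Between 25.4% and 34.2% of values under 20 steps lay within 0.02 steps of a whole multiple, so a single step does not describe all values, whole reads were not recovered, and the count-based tests planned for recovered reads were not run. Counting error therefore has no exact interval here, and the precision of each value is given as the SD over 3 libraries.

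Gene identifiers were named through a reference table, which covered 34495 of the 37441 rows; positions came from GENCODE release 29 on GRCh38. Of the 13889 rows tested, 597 had no name in the reference, and 63 of these were named by the deposited table of changed genes. A name from that source exists only for genes the authors called changed, so counts over such rows are selected. Among them were 24 further identifiers of HLA class II genes. Several genes of that region, such as HLA-DRA and TNF, were listed at 0 in all 6 libraries under their main identifier, and so was ISG15; a 0 in this table was therefore not read as absence of the transcript.

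Values were transformed as log2(normalized count + 1), and rows with a mean of at least 10 normalized counts over the 6 libraries were kept. Knockout was compared with control by limma's moderated test with an intensity trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all 13889 rows and a threshold of 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so limma's test, which pools the spread over genes, was used. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the figures.

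There were 26 gene lists, fixed before the data were examined along with the test, the alternatives and the rule for named genes. They covered sterol and fatty acid metabolism, melanoma cell states, signalling outputs, stress, immune genes, housekeeping groups and markers of other cell types. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, again with an estimated correlation, and with the fry rotation test, each adjusted over the 26 lists. For each list the number of genes passing was also computed with p-values adjusted over the list alone. The named genes were GRAMD1B and its relatives, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 100 normalized counts, and up to 4 members of each list with the smallest p. Genes outside that rule are named as chosen after their values were seen.

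The procedure was tested on simulated data of 13889 genes in 3 against 3 libraries. Over 5 runs, 32.4% of genes changed 1.5-fold were called, 59.2% at 2-fold, 89.2% at 4-fold and 94.4% at 8-fold, and 4.31% of calls were false. The simulated changes lay only in genes with a mean of at least 50 normalized counts. Genes were drawn independently, with no library standing apart from its group. These rates therefore need not hold for lower genes or for the real libraries, where control replicate 2 stands apart. Alternatives were other pseudocounts, filters and normalizations, a replicate block, a test without the trend, array weights, the removal of each library in turn and, added after seeing the data, the exclusion of identifiers that the reference did not name. TMM factors for the rescaling were computed on the normalized values with an implementation written for this purpose. No library or mapped column was left out of the main comparison.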

Results

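Gene expression was measured by RNA-seq in SKMEL2, an established human melanoma line that carries a mutated NRAS gene. The cells had received a lentiviral CRISPR vector with a non-targeting guide (control, 3 libraries) or with a guide against GRAMD1B (knockout, 3 libraries), followed by selection in puromycin for 10 days. GRAMD1B encodes a membrane protein of the endoplasmic reticulum that carries cholesterol from the plasma membrane at sites where both membranes meet. The deposited normalized counts summed to 22800000 to 24700000 per library, and 17086 to 17589 genes were above 0 in each. The comparison of knockout with control asked which transcripts change when GRAMD1B is targeted in these cells.

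GRAMD1B itself (ENSG00000023171, chromosome 11, 123358428 to 123627774 on GRCh38, plus strand) had 1247, 559 and 1206 normalized counts in the control libraries and 329, 327 and 387 in the knockout libraries. Its mean fell from 1004 ± 386 to 348 ± 34.2 normalized counts (SD, n = 3 per group), a log2 change of -1.44 (SE 0.30, adjusted p = 0.0400, limma). The groups did not overlap, with 387 in the highest knockout library and 559 in the lowest control library, but control replicate 2 lay closer to the knockout than to the other controls. Without control replicate 2 the log2 change was -1.82 (adjusted p = 0.000284). Leaving out any one of the other 5 libraries ended the call, with adjusted p from 0.115 without control replicate 1 to 0.159 without knockout replicate 1. A Cas9 cut need not lower a transcript, and the position of the guide is not given in the sources used here. Among its relatives, GRAMD1A had a log2 change of -0.04 (adjusted p = 0.834), GRAMD2B of -0.69 (adjusted p = 0.157) and GRAMD1C of -0.16 (adjusted p = 0.940), none past the threshold, and GRAMD2A lay under the filter. The value of GRAMD1C ranged from -0.96 without control replicate 1 to 0.89 without control replicate 2, neither past the threshold.

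In the knockout cells, CIITA, the transactivator of MHC class II genes, rose along with CD74 and HLA-DRB1, which serve antigen presentation on MHC class II. SOX10, CDH19 and TYR of the melanocyte lineage rose, and so did the cytokines CCL2, CXCL8 and IL1A. Single genes of the extracellular matrix and adhesion changed in both directions: EDIL3, COL6A2 and VCAN fell and LOXL3 and PLAT rose. As a set they formed no list of their own and were not tested together. LOXL3 and PLAT belong to the tested list of proteases and adhesion molecules, and COL6A2 to the tested mesenchymal list. Of 13889 genes tested, 776 changed at an adjusted p below 0.05 in limma's test, 476 higher and 300 lower in the knockout, and 248 of the higher and 117 of the lower changed at least 2-fold. The count rose to 2794 without control replicate 2 and fell when any other library was left out. It was 273 without control replicate 1, 246 without control replicate 3, and 167, 143 and 176 without knockout replicates 1, 2 and 3. A fit with fewer libraries also has less power, so these lower counts do not single out any of those libraries. Counts of single lists without control replicate 2, given below, are to be read against the 2794 of all 13889 genes that passed in that fit. VCAN was chosen after its values were seen.

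**Figure D1:**
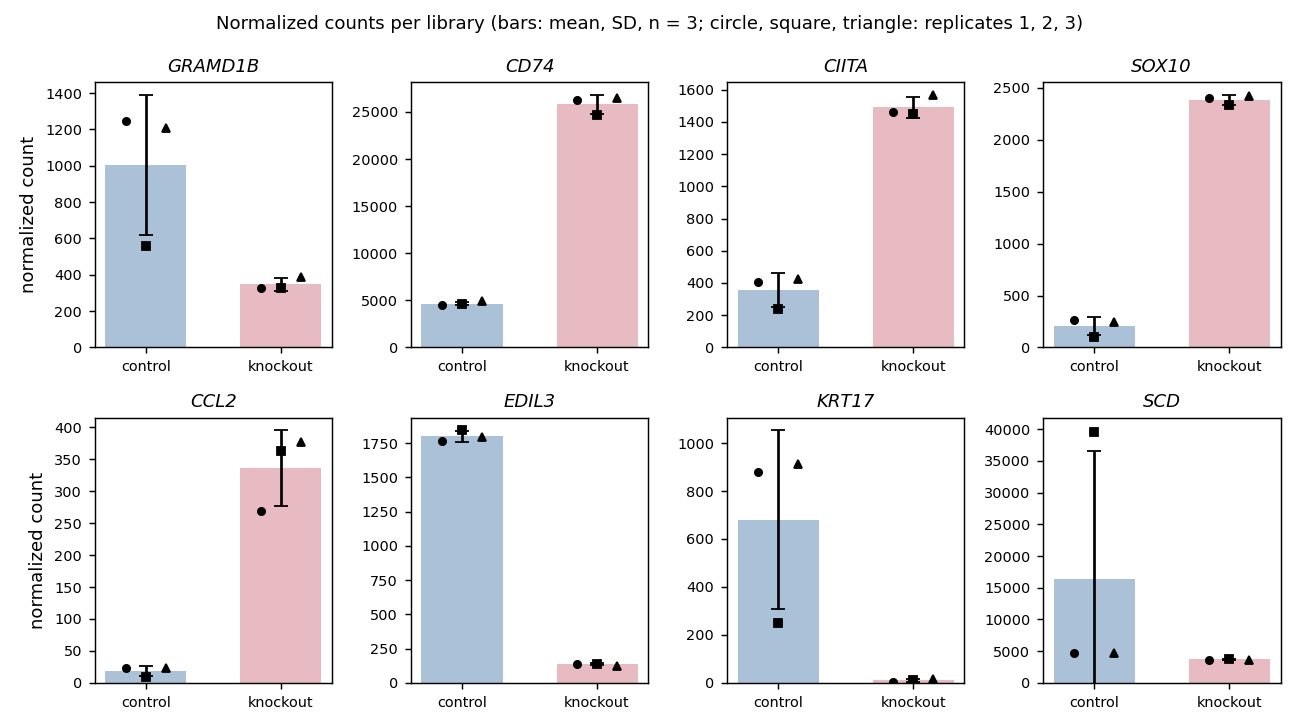
Normalized counts (vertical axes, linear) of 8 genes in control and knockout SKMEL2 cells, with bars for the mean, error bars for the SD (n = 3) and symbols for each library. CD74, CIITA, SOX10 and CCL2 lie higher and GRAMD1B, EDIL3 and KRT17 lower in each knockout library than in any control library, while SCD stands at 39649 in control replicate 2 against 4657 and 4718 in the other controls.

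CD74 (chromosome 5, 150401637 to 150412929), the invariant chain that chaperones MHC class II molecules, rose 5.55-fold from 4655 ± 197 to 25816 ± 984 normalized counts (SD, n = 3; log2 change 2.47, SE 0.07, adjusted p = 1.16e-05, limma). CIITA (chromosome 16, 10866222 to 10943021), the master activator of MHC class II transcription, rose 4.29-fold from 358 ± 104 to 1492 ± 65.1 (adjusted p = 0.00324). HLA-DRB1, which encodes a chain of the class II molecule, rose 9.84-fold under its main identifier (adjusted p = 0.00120), and HLA-DPB1 rose 3.83-fold (adjusted p = 0.0310). Reads of HLA genes were spread over near-identical copies, so the fold of any single identifier is uncertain. Over 28 class II identifiers of 12 genes, 27 rose and 0 fell in limma's test, by 3.83-fold to 39.8-fold with a median of 8.89-fold, but 24 of them were named only by the authors' deposited table, which lists changed genes alone. The upper end, HLA-DQA1, had 7.34, 0 and 13.9 normalized counts in the controls and ranged on the log2 scale from 4.16 without control replicate 2 to 6.10 without control replicate 3. It lost its call without control replicate 1 or any knockout replicate (adjusted p up to 0.124). Of the 4 named by the reference 3 rose, and HLA-DOA did not pass under that identifier (adjusted p = 0.0965).

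Of 10 measured genes of the antigen presentation list, 4 rose and 0 fell over all genes tested, and 5 rose and 1 fell when adjusted over the list alone. The list ranked higher by camera (adjusted p = 0.00391), a call lost with an estimated correlation (adjusted p = 0.188 with an estimated correlation). Of 8 tested identifiers of HLA class I genes 6 rose and 0 fell, with log2 changes of 0.52 to 2.89, but all 6 were named only by the authors' deposited table, and the 1 named by the reference did not pass (adjusted p = 0.126). B2M, the light chain of MHC class I, had a log2 change of 0.00 (adjusted p = 0.992), and NLRC5, the activator of class I transcription, one of -0.65 (adjusted p = 0.109). None of 28 measured interferon response genes passed limma's test with all libraries, but 1 higher and 4 lower passed without control replicate 2. The list was not called by camera in either fit (median log2 change -0.13, adjusted p = 0.167; without that control 0.01 and 0.616), but it was called lower at a minimum mean of 100 normalized counts (adjusted p = 0.0242). In that list IRF1 had a log2 change of -0.73 (adjusted p = 0.0687). B2M and NLRC5 were chosen after their values were seen. HLA-DPB1 lost its call when any library except control replicate 2 was left out (adjusted p up to 0.145, without knockout replicate 2).

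SOX10 (chromosome 22, 37970686 to 37987422), a transcription factor of neural crest and melanocyte identity, rose 12.5-fold from 206 ± 87.6 to 2385 ± 47.4 normalized counts (SD, n = 3; adjusted p = 0.00191, limma). CDH19, a cadherin of the Schwann cell and melanocyte lineages, rose 6.06-fold (adjusted p = 0.00196), and TYR, the rate-limiting enzyme of melanin synthesis, rose from 5.61 ± 2.90 to 74.9 ± 21.1 (adjusted p = 0.0109). MLPH, an adaptor of melanosome transport, rose 1.51-fold (adjusted p = 0.00957). MITF, the central regulator of melanocytes, varied between libraries (455 ± 332 in control, 376 ± 193 in knockout, adjusted p = 0.888), and MLANA lay under the filter at means of 2.75 and 3.46; both were chosen after their values were seen. Of 15 measured melanocytic differentiation genes, 6 rose and 1 fell (7 and 1 when adjusted over the list alone, 8 and 2 without control replicate 2), and camera placed the list higher (adjusted p = 0.000580). The call was lost with an estimated correlation (adjusted p = 0.188 with an estimated correlation). MIA, a secreted protein of melanoma cells outside the list, rose from 37.9 ± 11.1 to 376 ± 37.3. TYR and MLPH lost their calls without any one knockout library (adjusted p up to 0.0713 and 0.0681).

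Of 16 measured genes of the neural crest and dedifferentiation list 2 rose, NES by 1.97-fold and TEAD4 by 1.41-fold, and 0 fell; when adjusted over the list alone 3 rose and 1 fell. These counts rested on control replicate 2, without which 4 passed higher and 5 lower. The median log2 change was -0.05 while camera ranked the list higher, without a call (adjusted p = 0.573). Without that control the median was -0.21 and camera ranked it lower, again without a call (0.624). AXL, a receptor kinase of dedifferentiated melanoma, had 25481 ± 7655 normalized counts in control and 22079 ± 349 in knockout (adjusted p = 0.722), but a log2 change of -0.44 without control replicate 2 (adjusted p = 0.000717). NGFR and EGFR did not pass either (adjusted p = 0.264 and 0.408); these 3 were chosen after their values were seen. TEAD4 lost its call without any one library other than control replicate 2 (adjusted p up to 0.130).

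CCL2 (chromosome 17, 34255218 to 34257203), a chemokine that attracts monocytes, rose 18.2-fold from 18.7 ± 8.18 to 336 ± 59.0 normalized counts (SD, n = 3; adjusted p = 0.00202, limma). IL1A rose 6.44-fold, BIRC3, an inhibitor of apoptosis, 3.65-fold and CXCL8, a neutrophil chemokine, 3.45-fold, from 1182 ± 217 to 4061 ± 493 (adjusted p = 0.000457, 0.00120 and 0.00123). The cytokine LIF rose 2.46-fold (adjusted p = 0.0168). Of 20 measured genes in the NF-kappaB and cytokine list, 6 rose and 0 fell (9 and 0 when adjusted over the list alone, 13 and 0 without control replicate 2). Camera called the list higher (adjusted p = 2.25e-06), and the call was lost with an estimated correlation (adjusted p = 0.233 with an estimated correlation). LIF lost its call without control replicate 3, knockout replicate 2 or knockout replicate 3 (adjusted p up to 0.0917).

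EDIL3 (chromosome 5, 83940554 to 84384793), a secreted integrin ligand, fell from 1802 ± 40.7 to 135 ± 7.53 normalized counts (SD, n = 3; log2 change -3.73, SE 0.10, adjusted p = 1.16e-05, limma). COL6A2, COL6A1 and COL1A1, which encode collagen chains, fell by 1.18, 1.19 and 2.13 on the log2 scale, and PRRX1, a mesenchymal transcription factor, rose 3.23-fold. These were the calls of the mesenchymal list, 1 gene higher and 3 lower of 22 measured (1 and 5 when adjusted over the list alone, 3 and 10 without control replicate 2), and the list was not called by camera (adjusted p = 0.316). In the list of proteases and adhesion molecules, LOXL3, a lysyl oxidase, rose 8.32-fold from 93.7 ± 9.59 to 785 ± 40.9 (adjusted p = 0.000122), PLAT, the tissue plasminogen activator, 1.92-fold (adjusted p = 0.00120) and ADAMTS1, a matrix protease, 5.90-fold (adjusted p = 0.0113). PLAU, the urokinase, fell by 1.20 on the log2 scale (adjusted p = 0.00993). In all, 8 of the 32 measured genes of that list rose and 2 fell (14 and 2 when adjusted over the list alone, 13 and 4 without control replicate 2). Camera called the list higher (adjusted p = 0.00129), and the call was lost with an estimated correlation (adjusted p = 0.367 with an estimated correlation). COL1A1 lost its call without control replicate 1 or 3 or knockout replicate 1 or 2 (adjusted p up to 0.0948), COL6A1 without control replicate 1 or 3 or knockout replicate 2 or 3 (up to 0.0681), PRRX1 without control replicate 3 or any knockout replicate (up to 0.0853), PLAU without control replicate 3 or knockout replicate 2 (up to 0.0645) and ADAMTS1 without knockout replicate 2 or 3 (up to 0.0552).

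Of the marker lists of other cell types, the fibroblast list was called lower (2 of 6 measured genes fell, COL1A1 and PDPN, and 0 rose; 4 fell when adjusted over the list alone, 3 without control replicate 2; camera adjusted p = 0.00421), and the call was lost with an estimated correlation (adjusted p = 0.188 with an estimated correlation). The keratinocyte list was not called by camera (adjusted p = 0.233) but was called higher by fry (adjusted p = 0.0256): of 11 measured genes 4 rose, KRT14, PERP and KRT15 among them, and 1 fell (4 and 3 when adjusted over the list alone, 4 and 2 without control replicate 2). That was KRT17, an epithelial keratin, at 681 ± 372 normalized counts in control and 10.8 ± 6.70 in knockout (log2 change -5.83, adjusted p = 0.00418; -6.44 without control replicate 2). The keratinocyte list had a median log2 change of 0.22 and a mean of -0.45, and camera ranked it higher. Of 5 measured endothelial genes KDR rose and PECAM1 fell, also when adjusted over the list alone (camera adjusted p = 0.691). Of the immune cell markers 2 were measured, of which LYZ rose 3.64-fold from 17.4 ± 3.63 to 65.8 ± 12.4, also when adjusted over the list alone (camera adjusted p = 0.371, fry 0.0256). PDPN, KRT14, KRT15, PERP, KDR, PECAM1 and LYZ each lost the call in at least 3 of the 6 fits with a library left out (adjusted p up to 0.181, for KDR without knockout replicate 3).

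**Figure D2:**
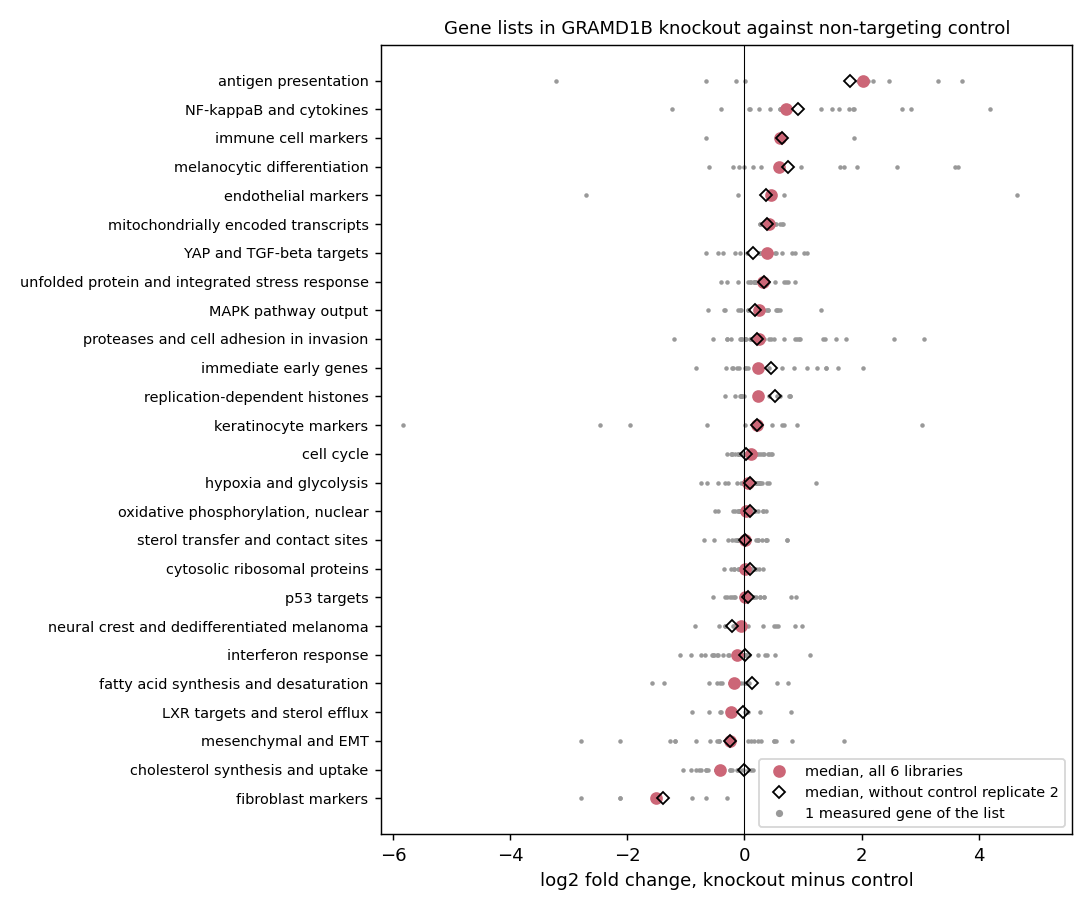
Log2 fold change of knockout against control (horizontal axis) for 26 gene lists, with a grey dot per measured gene, a filled circle for the median over all 6 libraries and an open diamond for the median without control replicate 2. The median of antigen presentation is 2.02 with all libraries and 1.80 without that control, whereas the median of cholesterol synthesis and uptake goes from -0.41 to 0.00.

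No gene of the cholesterol synthesis and uptake list, which holds the enzymes and regulators controlled by sterol levels, passed limma's test with all libraries: 0 of 25 rose or fell, over all genes and when adjusted over the list alone. Without control replicate 2, 3 passed higher and 4 lower. SREBF2, the main transcriptional activator of the pathway, had 3581 ± 1354 normalized counts in control and 2044.5 ± 41.8 in knockout (SD, n = 3; adjusted p = 0.109), and a log2 change of -0.45 without that control (adjusted p = 0.00288). Camera called the list lower (adjusted p = 0.0122), but the call was lost with an estimated correlation (adjusted p = 0.748 with an estimated correlation) and without control replicate 2 (median log2 change 0.00, adjusted p = 0.739). In control replicate 2 all 25 genes lay above both other controls, by a median of 2.03-fold, and the desaturase SCD, chosen after its values were seen, had 39649 normalized counts there against 4657 and 4718. LXR targets and sterol efflux genes gave 0 calls of 10 in either direction (0 higher and 1 lower when adjusted over the list alone and without control replicate 2, camera adjusted p = 0.235). Camera called that list lower at a minimum mean of 100 (adjusted p = 0.0270) and without control replicate 1 (adjusted p = 0.0489). Of 14 fatty acid synthesis genes ELOVL1 rose 1.46-fold and PNPLA3 fell by 1.58 on the log2 scale (1 and 2 when adjusted over the list alone, 2 and 3 without control replicate 2, camera adjusted p = 0.316). Of 28 genes of sterol transfer and contact sites OSBPL3, an oxysterol-binding protein, rose 1.30-fold and 0 fell (1 and 0 when adjusted over the list alone, 6 and 2 without control replicate 2). Camera did not call that list (adjusted p = 0.648), whereas fry called it higher (adjusted p = 0.000220), at a median log2 change of 0.01. ELOVL1, PNPLA3 and OSBPL3 each lost the call without any one knockout library (adjusted p up to 0.144).

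**Figure D3:**
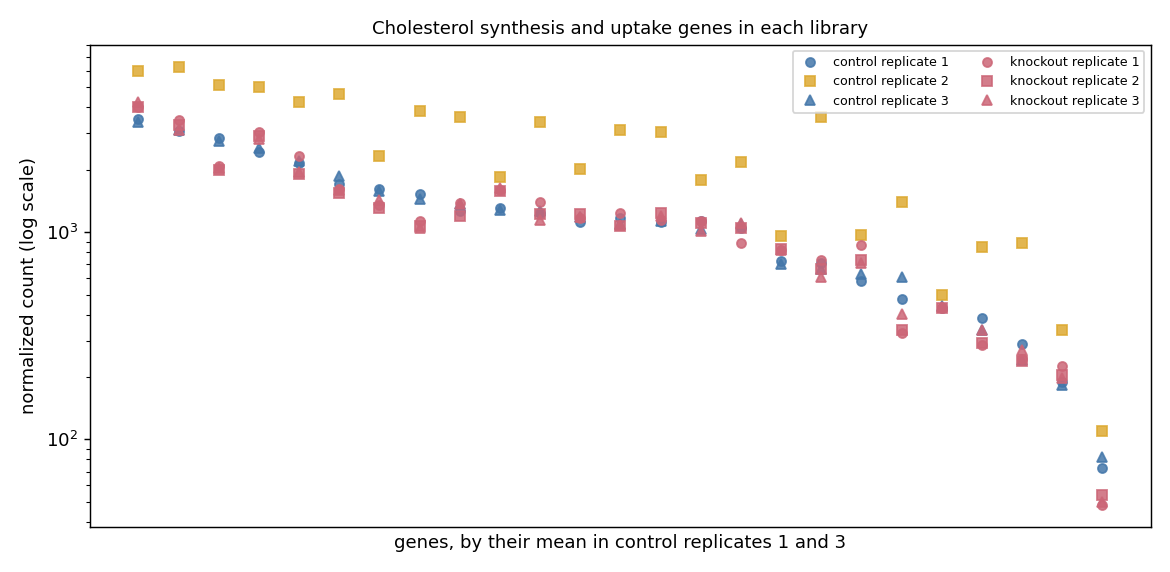
Normalized counts (vertical axis, log scale) of the 25 measured genes of cholesterol synthesis and uptake in each of the 6 libraries, with genes along the horizontal axis by their mean in control replicates 1 and 3. Control replicate 2 (yellow squares) lies above both other controls for all 25 genes, by a median of 2.03-fold.

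Transcripts of the mitochondrial genome took 5.66% ± 0.289 of normalized counts in control and 7.11% ± 0.666 in knockout libraries (SD, n = 3). Of the 13 measured transcripts MT-ND1, MT-ND3 and MT-ND4, subunits of respiratory complex I, rose by 1.58-fold, 1.53-fold and 1.46-fold, 0 fell, and all 13 rose when adjusted over the list alone and 9 without control replicate 2 (camera adjusted p = 2.25e-06, lost at an adjusted p = 0.367 with an estimated correlation). Nuclear genes of oxidative phosphorylation gave 0 calls of 35, also when adjusted over the list alone, and 4 higher and 1 lower without control replicate 2 (camera adjusted p = 0.542). In the unfolded protein and integrated stress response list 5 of 27 genes rose and 0 fell (6 and 0 when adjusted over the list alone, 10 and 1 without control replicate 2), among them XBP1, a transcription factor of the unfolded protein response, by 1.43-fold and PHGDH, an enzyme of serine synthesis, by 1.67-fold (camera adjusted p = 0.000502, lost at an adjusted p = 0.188 with an estimated correlation). In the MAPK output list 4 of 19 rose and 0 fell (6 and 0 when adjusted over the list alone, 7 and 0 without control replicate 2): LIF, SPRY2, EPHA2 and DUSP6, the last a phosphatase that inactivates ERK, by 1.47-fold. That list's camera call (adjusted p = 0.0458) was lost with an estimated correlation (adjusted p = 0.276 with an estimated correlation) and without control replicate 3, knockout replicate 1 or knockout replicate 3 (adjusted p = 0.123, 0.0519 and 0.0756). The calls of MT-ND1, MT-ND3, MT-ND4, XBP1, PHGDH, SPRY2, EPHA2 and DUSP6 were each lost in at least 4 of the 6 fits with a library left out (adjusted p up to 0.221, for MT-ND4 without knockout replicate 2).

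Camera did not call the remaining lists. Of 19 YAP and TGF-beta targets 3 rose and 2 fell, also when adjusted over the list alone, and 4 and 5 passed without control replicate 2 (camera adjusted p = 0.133). CCN2, a matricellular protein, rose 1.56-fold and ANKRD1, a transcriptional cofactor, 2.03-fold, while the receptor TGFBR1 and the scaffold AJUBA fell by 0.66 and 0.46 on the log2 scale. CCN2 and ANKRD1 lost their calls without knockout replicate 2 (adjusted p = 0.0547 and 0.0536), TGFBR1 without control replicate 1 or knockout replicate 1 or 3 (up to 0.0933), and AJUBA without any one library other than control replicate 2 (up to 0.114). Among 21 p53 targets GADD45A rose 1.74-fold and TNFRSF10B 1.26-fold, 0 fell, and the counts were 2 and 0 when adjusted over the list alone and 3 and 1 without control replicate 2. Camera did not call the p53 list (adjusted p = 0.543) and fry called it higher (adjusted p = 0.0461). Cell cycle genes gave 0 calls of 37 (camera adjusted p = 0.151), hypoxia and glycolysis genes 0 of 30 (0.316), immediate early genes 0 of 20 (0.316), ribosomal protein genes 0 of 41 (0.941) and replication-dependent histones 0 of 15 (0.371), each also 0 when adjusted over the list alone. Those zeros rested on control replicate 2: without it 9 cell cycle genes passed higher and 4 lower, 6 and 0 of hypoxia, 8 and 1 of the immediate early genes, 10 and 1 of the ribosomal protein genes and 3 and 0 of the histones. In that fit 2794 of all 13889 genes passed, so a rise in such counts was not particular to these lists. Ribosomal protein genes had a median log2 change of 0.01 while camera ranked them lower. In control replicate 2 the immediate early genes lay a median of 2.17-fold and the histones 1.94-fold from the other controls. Without that library immediate early genes, histones and hypoxia genes were called higher by camera (adjusted p = 0.00234, 0.00644 and 0.0336), and so were ribosomal protein genes (0.0408). TNFRSF10B, a death receptor, lost its call without any one library other than control replicate 2 (adjusted p up to 0.178).

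Among the other genes with the largest changes, FLRT3, EPB41L3 and GJB1 rose 17.8-fold, 9.63-fold and 9.25-fold, and FOXS1, TENM2, CACNG4 and CFI fell by 3.26, 3.16, 2.96 and 2.70 on the log2 scale. GAGE12H, one of a family of near-identical cancer-testis genes, was listed at 0 in the 3 control libraries and at 266, 202 and 245 normalized counts in the knockout libraries. VPS52, which lies at 33250272 to 33272047 on chromosome 6 in the region with alternate copies, was listed at 396, 398 and 232 in the controls and at 0 in the knockouts. No fold is given for GAGE12H or VPS52, because both have near-identical copies. MAGEA4, a cancer-testis gene on chromosome X, fell by 3.43 on the log2 scale (SE 0.25, limma). FLRT3 ranged on the log2 scale from 3.14 without control replicate 2 to 4.93 without control replicate 1, against 4.16 with all libraries. It lost its call without control replicate 3 or any knockout replicate (adjusted p up to 0.146), CFI without any knockout replicate (up to 0.101) and TENM2 without knockout replicate 1 or 2 (up to 0.0604).

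By chromosome, the median log2 change of genes with a mean of at least 50 normalized counts was -0.19 on chromosome 14 (392 genes), -0.17 on chromosomes 4 and 5 (415 and 521 genes), -0.13 on chromosome 15 (374 genes) and 0.19 on chromosome 13 (193 genes). The controls differed among themselves there: against the mean of all libraries, control replicate 2 had a median of -0.03 on chromosome 4, with 0.15 and 0.13 in control replicates 1 and 3 and -0.10 to -0.06 in the knockouts. On chromosome 5 it had 0.00, against 0.14 and 0.11, and on chromosome 13 it had -0.24, against -0.06 and -0.04. On chromosome 14 the 3 controls lay at 0.07, 0.13 and 0.08 and the knockouts at -0.08, -0.08 and -0.11. The most extreme run of 50 neighbouring genes spanned 175477062 to 180578405 on chromosome 5, from SFXN1 to CNOT6, with a median log2 change of -0.37 and 46 of 50 genes below 0. The run from SLAIN1 to ADPRHL1 on chromosome 13 had a median of 0.26, with 7 of 50 below 0. These runs were singled out after the values were seen.

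**Figure D4:**
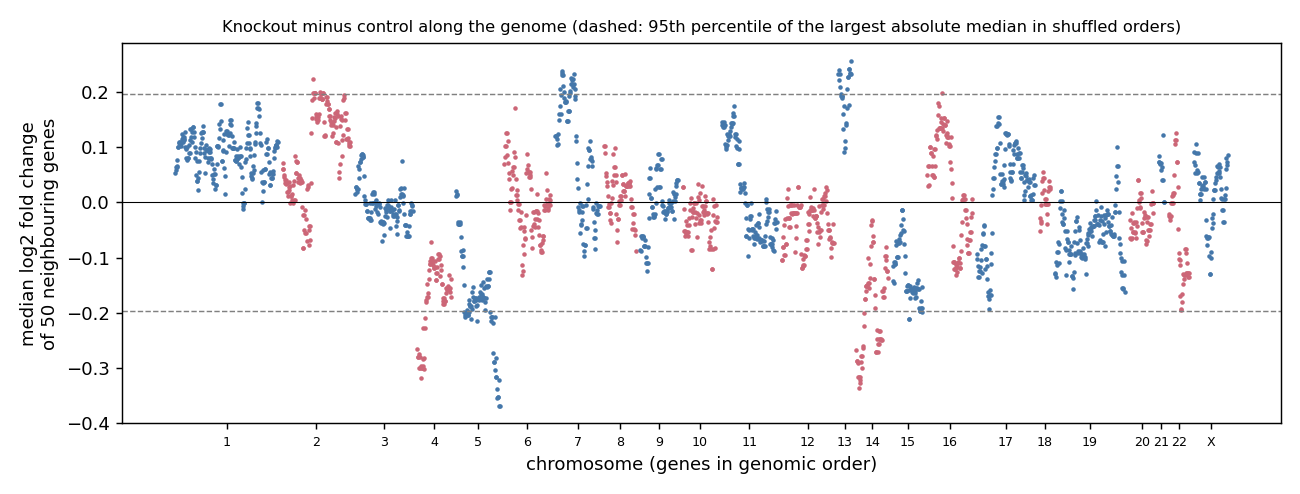
Median log2 fold change of knockout against control (vertical axis) over runs of 50 neighbouring genes in genomic order (horizontal axis), with colours alternating by chromosome and dashed lines at 0.197 above and below 0, the 95th percentile of the largest absolute median in 200 shuffled gene orders. Runs on chromosomes 4, 5 and 14 lie below the lower line, the most extreme at -0.37, and runs on chromosome 13 above the upper line.

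The authors' deposited table listed 1652 genes, 909 higher and 743 lower in the knockout. Of the 1636 genes of the authors' deposited table that were tested here, all moved in the direction listed there and 774 passed limma's test, while 2 genes passed here alone. The authors' deposited table gave GRAMD1B a log2 change of -1.53 with an adjusted p of 3.41e-06. The authors' deposited table rests on the same 6 libraries, so it is no independent evidence for any gene.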

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

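The alternatives were chosen before the data were examined, except the exclusion of identifiers the reference did not name, which was chosen after seeing the data. Other pseudocounts, no filter, a minimum mean of 100, TMM rescaling, quantile normalization and reference names only gave 630 to 813 changed genes against 776. Past the threshold were 91 genes named by the rule or chosen after their values were seen. Of these 91 genes, 0 reversed under any of these settings or the alternatives below and 49 lost the call under at least 1, 32 of them also with all libraries kept. All 91 had passed on these same libraries, so reversals were unlikely from the start. The test without the trend gave 511 genes (189 lower) and GRAMD1B an adjusted p of 0.0874. That setting cannot alter the fitted log2 change, which was -1.44 for GRAMD1B. Array weights gave 3763 genes (1912 higher, 1851 lower; 474 and 260 at least 2-fold), and the cholesterol list an adjusted p of 0.524, and called immediate early genes and histones higher (0.0149 each). A minimum mean of 100 gave 136 genes at least 2-fold higher and 77 lower, since fewer genes were tested, and called the interferon and LXR lists lower (0.0242 and 0.0270). Quantile normalization gave the MAPK list an adjusted p of 0.1002.

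The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0366, -0.0102 and 0.0490. With a replicate block 273 genes passed (185 higher and 88 lower, of which 146 and 58 at least 2-fold). GRAMD1B lost its call there (adjusted p = 0.0548), and the MAPK list had an adjusted p of 0.0585. A block in this balanced design cannot alter the fitted log2 change, which was -1.44 for GRAMD1B. The block leaves fewer residual degrees of freedom.

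With an estimated correlation 0 of the 26 lists were called, against 9 with the preset one and 12 by fry. Camera compares a list with all other genes, whereas fry asks whether the list changed at all, so their calls answer different questions. Fry did not call cholesterol synthesis and called 4 lists that camera did not: sterol transfer (0.000220), p53 targets (0.0461), keratinocyte markers and immune markers (0.0256 each). The adjusted p with the estimated correlation was 0.188 for antigen presentation, melanocytic differentiation, fibroblast markers and the unfolded protein list. It was 0.233 for NF-kappaB and cytokines, 0.276 for MAPK output and 0.367 for mitochondrial transcripts and for proteases and adhesion. For cholesterol synthesis it was 0.748, and fry gave 0.438. The estimated correlation was below the preset 0.01 for fibroblast markers (-0.123), antigen presentation (-0.0991) and MAPK output (0.00347). Correlation between genes therefore does not account for those lost calls. With an estimated correlation camera also uses fewer degrees of freedom, set by the number of libraries, which raises p at the same correlation. A call lost in that setting is therefore no sign by itself of correlated genes. The 2 parts were not separated for each list. In the other lists called with the preset one, the estimate ran from 0.0275 for the unfolded protein list to 0.961 for cholesterol synthesis.

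With 1 library left out, the count ranged from 143 (without knockout replicate 2) to 2794 (without control replicate 2), higher genes from 98 to 1437 and lower genes from 45 to 1357, and at least 2-fold from 85 to 405 higher and from 35 to 180 lower. The share of calls that were higher was 61.3% with all libraries, 51.4% without control replicate 2 and 73.6% without control replicate 3. GRAMD1B ranged from -1.82 to -1.24, and the fits that ended its call from -1.52 to -1.24. The adjusted p of the MAPK list ranged from 0.00873 to 0.123, in the fits that ended its call from 0.0519, and that of the cholesterol list from 0.000523 to 0.739. The ribosomal protein list ranged from 0.0408 to 0.994 and turned from lower to higher without control replicate 2 (0.0408). Apart from the smaller number of libraries, the cause was not tested. Count-based tests with edgeR and DESeq2, planned for recovered whole reads, were not run.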

Other observations

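Tests of immune cells, of a mixed control and of depth, and the comparison with other splits, were chosen after the results were seen; the test of neighbouring genes was written before its result was seen, after 2 lower genes had been noticed on chromosome 14.

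All genes of this paragraph except MAGEA4 were chosen after their values were seen, so they stand as single genes, with no test of any group. S100B, a calcium-binding protein used as a marker of melanocytic and Schwann cells, rose 8.86-fold from 70.8 ± 30.1 to 606 ± 153 normalized counts (SD, n = 3; adjusted p = 0.00446, limma). Of single cancer-testis genes on chromosome X, SSX1 rose 4.38-fold from 322 ± 23.7 to 1415 ± 133 (adjusted p = 0.000192), GAGE1 rose 5.16-fold and GAGE2A 3.35-fold, while MAGEA4 fell from 246 ± 20.4 to 22.3 ± 4.99. Reads of GAGE and SSX genes can be shared within each family, so their single values are uncertain. The Wnt ligands WNT7B and WNT9A fell by 1.49 and 1.54 on the log2 scale, and the transcription factor MSX1 by 1.51, and NREP, a neuronal regeneration protein, by 2.01. IGFBP3 and ESM1, secreted proteins, rose 4.47-fold and 7.40-fold.

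The first pattern is the rise of CIITA, CD74 and HLA class II identifiers; whether reads also moved between near-identical HLA copies was not tested and stays open. Immune cells in the knockout cultures would bring their own transcripts, yet the 7 immune cell markers above 0 outside that region together rose by 0.211% of the CD74 rise. Without LYZ their sum moved by -0.0175% of that rise, because CSF1R fell from a mean of 46.8 to 31.9. The rest of the 7 lay under the filter, with higher means in knockout: ITGAM 0.465 to 6.12, CD79A 1.81 to 4.10, CD14 0.281 to 1.83, CD3D 4.64 to 5.95 and PTPRC 0.580 to 1.01. The other 7 of the 14 listed markers were at 0 in all 6 libraries, which was not read as absence, so they say nothing here. The marker set and the bound of this test, 1%, were set after a first version with another marker set and a bound of 0.1% had been run, and 0.211% would have missed that first bound. As a hypothesis, the rise of CIITA may follow from the loss of GRAMD1B, or from a difference between the infected pools that arose independently of it, and with 1 guide named per group the 2 readings cannot be separated here.

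The second pattern is control replicate 2, in which 350 of 10867 genes with a mean of at least 100 lay at least 2-fold outside both other controls, 148 below and 202 above. Counting noise from depth argues poorly for this, since 73 genes with a mean of at least 1000 did so, against 1 and 2 in the other controls. Knockout cells mixed into this library were tested because GRAMD1B lay 0.760 of the way to the knockout there. Over 299 genes that differed at least 2-fold between the other controls and the knockout, the median share of the way was 0.128 (bootstrap interval 0.0338 to 0.233). SCD stood at 39649 against 3689 ± 121 in the knockout, so mixing alone does not explain how this library stands apart. The interval lies above 0, so a small share of knockout cells in it stays open. No biological explanation was tested, since the labels name no difference between the controls; besides the lists named in the report, LXR targets lay a median of 1.95-fold, fatty acid genes 1.74-fold and fibroblast markers 1.61-fold of the other controls, YAP and TGF-beta targets 0.670-fold, and 38 of 41 ribosomal protein genes lay above both.

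The third pattern is the count of changed genes and its spread along chromosomes. The real split gave 776 genes and the highest of the other 9 splits gave 3; 1 of 10 splits gave as many, and 10 splits are too few for a share below 0.05. Genes whose groups did not overlap made up 30.8% of those tested, against 10% by chance. A copy number difference between the cell pools was predicted to shift runs of neighbouring genes together, and the largest absolute median over 50 neighbouring genes was 0.369, above the 95th percentile of 0.197 in 200 shuffled orders and above the 0.160 to 0.251 seen in the other 9 splits. As a hypothesis, part of the small changes on chromosomes 4, 5, 13 and 14 may reflect cells of different clonal makeup, but the controls differed among themselves (-0.24 in control replicate 2 against -0.06 and -0.04 on chromosome 13), which 2 uniform pools would not give, while on chromosome 14 all controls (0.07 to 0.13) lay above all knockouts (-0.11 to -0.08); DNA was not measured, and shared regulation of neighbouring genes stays open.

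Beyond GAGE12H and VPS52, HEPH, MRGPRX4, ENSG00000269547 and a copy of NLRP2 were listed at 0 in 3 libraries of one group and above 10 in each library of the other; the real split gave 6 such identifiers and the other splits 2 to 7.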
